A study of Mus musculus with 12 samples.

How the data were processed

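The deposited files hold the signal of each spot of 12 one-colour Agilent mouse miRNA arrays as read by Feature Extraction 10.2.1.3. Per the file headers the deposited intensity values are processed signals, from which the authors' run of that software had subtracted a spatially detrended background, with multiplicative detrending off and no scaling between arrays. The value table of the series equals these processed signals (largest difference 0), and its medians of 1.20 to 1.97 are those of unscaled values, most of which are background.

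Control spots were left out, as were 284 to 508 spots per array that the software marked as uneven or as outliers among their replicates. An array has 12493 spots, controls included, and those other than controls belong to 1712 probes of 577 miRNAs. The spots of a probe were averaged, and each array was divided by its 75th percentile over the 170 probes that were well above background on all 12 arrays. A floor of 0.0209 (log2 -5.58), the median over arrays of the lowest value that was well above background, replaced lower values, and log2 was taken. Values at the floor have no order among themselves. The brightest probe stood for each miRNA, and 15.2 to 21.1% of probes were well above background on an array. Of 191 miRNAs with 2 probes, 5 gave differences of opposite sign that were both over 0.1 (log2), and the median gap between probes was 0.118 (log2).

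A miRNA was tested if it was well above background on all 3 arrays of at least 1 line, which left 224. limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8, and statmod, version 1.5.0) fitted the 4 lines to all 12 arrays, leaving 8 residual degrees of freedom, and called a difference at a Benjamini-Hochberg adjusted two-sided p below 0.05, separately for each comparison. The median SE of a difference was 0.0431 for 4T1 against the mean of the 3 other lines and 0.0528 for 2 lines. Where a miRNA was not well above background on any array of 1 side, its fold is a lower bound. It is the mean level of the other side over the lowest level well above background on each unread array, or over the miRNA's own floored level there where that is higher. Against the mean of the 3 lines a rise with 1 of them unread is bounded in the same way, and a fall with 1 of them unread has no bound. For 4 of the named folds (miR-148a, miR-146b and miR-449a in 4T1 and miR-10b in 168FARN) 2 arrays were marked as well above background while all 3 read the floor, and the fold over the floor is given as a lower bound.

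The miRNAs named were picked by rule. For 4T1 against the mean they were the 10 highest and 10 lowest that passed, were measured in 4T1 and at least 2 other lines and whose 4T1 arrays lay beyond the 9 others. For 2 lines they were the 5 highest and 5 lowest measured in both lines with arrays that did not overlap. The 5 largest bounds in each direction were added, with members of the lists in order of adjusted p.

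The lists cover the miR-200 family and its passenger strands, the miR-183 cluster, other epithelial miRNAs, mesenchymal and fibroblast miRNAs, miR-17-92 and its paralogs, let-7, miR-34, miR-15/16, miR-29, miR-30, miR-23/24/27, the clusters of miR-99, miR-100 and miR-125, miR-221/222, the Dlk1-Dio3, Sfmbt2, stem cell (miR-290 and miR-302) and X-linked Fmr1-proximal clusters, haematopoietic, endothelial, muscle, nervous system, liver and pancreas and viral miRNAs, and miRNAs reported to promote or to suppress breast cancer metastasis. Of these 26 lists 16 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01 between members. The list difference is the mean over the members minus the mean over the other tested miRNAs, while the medians and means given with the counts are those of the members' own differences.

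Scaling, floor, filter, tests, lists, naming rule and the alternatives were chosen before the data were examined, except the fit without the 67NR arrays and the fit with a term for the first place of a row on a slide. The alternatives were other scalings (the 75th percentile of all probes, none, quantile), the normexp background correction with an offset of 50, the gene-level total signal, the mean of all probes of a miRNA, other filters and floors, a slide term, 1 slide alone, the replicate number as a block, each array left out in turn, only the lines compared, a minimum difference, a trended robust variance, and camera with an estimated correlation or fry in its place.

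As a check of the fit, 20 miRNAs each were changed by 1.2, 1.5 and 2-fold in the 4T1 arrays of a simulated set of 12 arrays with the spread of the real ones and no other differences. For 4T1 against the mean, 19, 20 and 19 of them were recovered, with 2 false calls among 224 miRNAs. For 4T1 against 4TO7, 18, 20 and 20 were recovered, also with 2 false calls. When let-7 alone was shifted by 1 (log2), it was the 1 list called of 16. The simulated values were not floored and held no unread line, so the check does not cover miRNAs with an unread side.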

Results

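The level of 577 microRNAs (miRNAs), 567 of the mouse and 10 of mouse viruses, was measured in 4 mouse breast cancer cell lines with 12 one-colour Agilent mouse miRNA arrays, 3 for each line. Such an array carries short probes to which labelled RNA binds, and the brightness of a spot is read as the amount of the miRNA. The lines 67NR, 168FARN, 4TO7 and 4T1 come from breast tumours that arose spontaneously in BALB/c mice, and the labels call 4T1 metastatic and the other 3 lines non-metastatic. Total RNA taken with Trizol was hybridised at 100 ng per array. The labels do not say whether the 3 repeats of a line are separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Levels are given as log2 of the scaled signal, ± the standard deviation (SD) over 3 arrays, and differences as log2 ± their standard error (SE), with n = 3 arrays per line throughout. A difference called "at least" a fold has a side with a line that was not read, that is, not well above background on any array or at the floor on all of them. That line is taken at the lowest level read on each of its arrays or at its own level, floored at -5.58, whichever is higher. Elsewhere unread levels below the floor enter the fits at it, where arrays show no spread, and unread levels above the floor enter as they are. A p-value beside an "at least" fold is that of the floored difference, not of the bound, and may be too small. Positions are those of the probe targets in genome build mm9.

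Between 141 and 161 miRNAs were well above background on the 67NR arrays, 176 to 191 on the 168FARN arrays, 147 to 158 on the 4TO7 arrays and 166 to 187 on the 4T1 arrays. The 75th percentile of the bright probes, by which each array was scaled, was 358 to 460 signal units on the 67NR arrays, 791 to 1213 on those of 168FARN, 600 to 671 on those of 4TO7 and 889 to 1136 on those of 4T1, and no spot was saturated. Over the 224 tested miRNAs, arrays of 1 line correlated at 0.993 to 1.000 (Pearson's r across miRNAs, which are not independent replicates). 4TO7 and 4T1 arrays correlated at 0.959 to 0.965, 168FARN and 4T1 arrays at 0.862 to 0.874, and 168FARN and 4TO7 arrays at 0.837 to 0.850. The 67NR arrays stood apart, at 0.626 to 0.636 with 4T1, 0.611 to 0.620 with 4TO7 and 0.539 to 0.551 with 168FARN. In 67NR 68 miRNAs were over 2-fold higher and 33 over 2-fold lower than in each other line, against 29 and 11 in 168FARN, 2 and 3 in 4TO7 and 2 and 0 in 4T1. Among the control probes, the 4 named hur_5 had a mean of 180 to 206 on the 67NR arrays and of 1.25 to 6.36 on the other 9. The 67NR arrays shared a slide with 168FARN replicate 1, and the other 8 arrays were on a second slide.

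**Figure D1:**
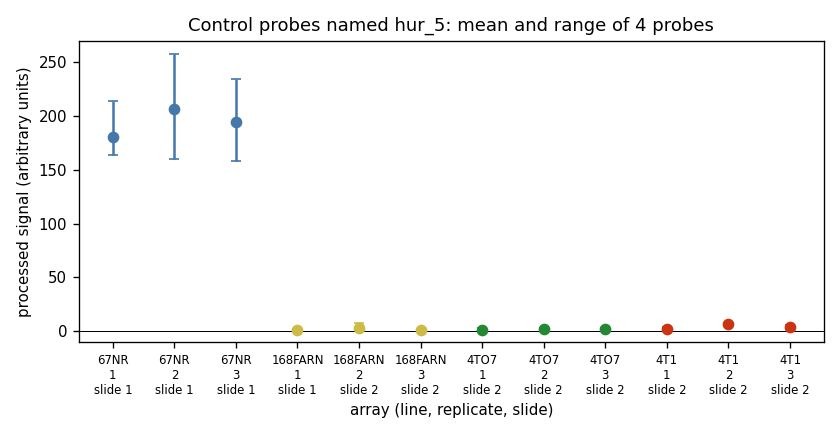
Processed signal (arbitrary units) of the 4 control probes named hur_5 on each of the 12 arrays, as the mean and range of the probes. The means of the 3 arrays of 67NR sit between 180 and 206, and those of the other 9, 168FARN replicate 1 on the same slide included, between 1.25 and 6.36.

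The first comparison asked which miRNAs the metastatic line 4T1 held at another level than the average of the 3 non-metastatic lines. miR-125b-5p (chromosome 16, 77646529 to 77646545), which shares its cluster with a let-7 gene, was highest over that average, by 2.45 ± 0.03 (SE; 5.45-fold; adjusted p = 1.45e-13). Its level ran from -1.72 ± 0.06 (SD) in 67NR through 2.82 ± 0.05 in 168FARN and 3.23 ± 0.01 in 4TO7 to 3.89 ± 0.07 in 4T1. miR-155 (chromosome 16, 84714393 to 84714410), known from activated immune cells and raised in many tumours, rose at least 4.07-fold (adjusted p = 2.82e-12), with 67NR unread. miR-100 (chromosome 9, 41339523 to 41339541) rose by 1.65 ± 0.05 (3.14-fold). miR-101a (chromosome 4, 101019562 to 101019582), a repressor of the chromatin enzyme Ezh2, fell by 1.45 ± 0.04 (2.74-fold; adjusted p = 3.44e-11), with the 4T1 arrays below all 9 others. miR-10a, miR-10b and miR-196a, which lie within the Hox gene clusters, and miR-342-3p and miR-218 were read in 67NR but not in 4T1 or 4TO7, so no fold against the average can be given.

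Among the others that were higher, miR-181d rose 2.59-fold and miR-23b 2.28-fold. With 67NR unread, miR-500 rose at least 2.43-fold, miR-674* 2.02-fold, miR-101b 1.89-fold, and miR-21* and miR-362-3p 1.83-fold each. miR-181c rose at least 1.89-fold and miR-301b at least 1.79-fold, and both were well above background only on the 4T1 arrays. Other miRNAs with the 4T1 arrays below all 9 others included miR-128 (2.62-fold), miR-148b (2.55-fold), miR-7a (2.33-fold), miR-378 (2.28-fold), miR-361 (2.26-fold), miR-1224 (2.23-fold), miR-9* (2.19-fold), miR-487b (2.15-fold) and miR-296-5p (2.13-fold). With the normexp background correction the differences of miR-21* (0.09), miR-362-3p (0.07), miR-181c (0.01) and miR-301b (0.07) no longer passed.

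4 of the 16 lists of related miRNAs that could be tested differed from the other miRNAs in this comparison, and none of these calls held when the correlation within a list was estimated (adjusted p = 0.457 to 0.624 with an estimated correlation). The let-7 family, which holds back growth genes such as Ras and Hmga2, was higher (8 higher and 1 not passing, of 9; median 1.04; adjusted p = 0.0013), with let-7d at 1.66 ± 0.06, let-7i at 1.55 ± 0.05 and let-7e, not passing, at 0.04 ± 0.06. The miR-23/24/27 clusters were higher (5 of 5; median 0.75; adjusted p = 0.0089), with miR-23b at 1.19 ± 0.05 and miR-27b at 1.10 ± 0.07. The cluster in an intron of the imprinted gene Sfmbt2 (chromosome 2, 10389446 to 10430967) was higher (10 higher, 2 lower and 1 not passing, of 13; median 0.61 with unread levels at the floor; adjusted p = 0.00055). Its member miR-669a was at the floor in 67NR and 168FARN, -1.81 ± 0.06 in 4TO7 and -2.64 ± 0.04 in 4T1. Second, dimmer probes gave -0.15 for miR-669b, -0.10 for miR-467e, -0.17 for miR-467c and -0.03 for miR-467a*. Their brightest probes gave 0.61, 0.45, 0.36 and 1.55. The second probes of miR-669a, miR-466e-3p, miR-297a, miR-467b and miR-467a stayed positive. The X-linked cluster near Fmr1 (chromosome X, 64029935 to 64079192), known from the testis, was lower (16 of 16; median -0.78; adjusted p = 0.00675), a value set by the floor, since 168FARN was the only line whose arrays all read it. Adjusted over the list alone, the counts were the same as those over all tested miRNAs. By list these values were adjusted p = 0.624 with an estimated correlation for let-7 (range over the alternatives of the same test 3.04e-07 to 0.774), 0.457 for miR-23/24/27 (5.78e-05 to 0.522), 0.457 for Sfmbt2 (2.21e-08 to 0.457) and 0.624 for the X-linked cluster (4.89e-07 to 0.624).

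The 67NR arrays, which stood apart, carried a large part of this comparison. Without them (an alternative chosen after the data were seen) the mean of the let-7 family lay -0.03 from that of the other tested miRNAs, and its call and those of Sfmbt2 (0.46) and miR-23/24/27 (0.54) ended. The X-linked cluster stayed lower (-1.12; adjusted p = 9.8e-05 by camera), and the miR-17-92 cluster became higher (0.53; 0.00241) and the mesenchymal list lower (-0.85; 0.0383). These calls rest on the preset correlation, and an estimated one was not tried without 67NR. With 67NR left out 167 of 205 miRNAs differed, and of the 177 called before, 114 kept their direction and call and 36 were called in the other direction. A doubled floor also ended the calls of Sfmbt2 and the X-linked cluster, and no scaling that of miR-23/24/27.

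In all, 196 of 224 miRNAs (87.5%) differed from the average of the 3 other lines by limma at an adjusted p below 0.05, 63 higher and 133 lower, 31 and 35 of them at least 2-fold. Over all 224 tested miRNAs the 4T1 arrays lay above or below all 9 others in 39, each of them called. Chance would give 0.909% of unselected miRNAs. The 224 were picked for being read on all arrays of a line, which favours arrays that lie apart, here and below. With slide as a term 192 differed (61 higher and 131 lower), all 196 kept their direction, and the list differences, each the mean of a list less that of the other tested miRNAs, moved from 1.12 to 1.15 for let-7, 0.98 to 1.01 for miR-23/24/27, 0.91 to 0.93 for Sfmbt2 and stayed at -0.64 for the X-linked cluster. No slide holds all 4 lines, so there is no value within a slide. The split into higher and lower depended on the scaling, at 93 and 98 with the 75th percentile of all probes, 111 and 66 with no scaling and 89 and 106 with quantile scaling, and it was 38 and 159 with the normexp correction.

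Several lists did not differ as a whole from the other miRNAs. The mesenchymal and fibroblast list had 6 lower of 6 (adjusted p = 0.123), the miR-15/16 family 6 lower of 6 (0.123), with miR-195 at -1.59 ± 0.07, and miR-17-92 with its paralogs 11 lower and 1 higher of 13 (0.165). The miR-183 cluster had 2 higher of 3 (0.165), with miR-182 higher by at least 2.24-fold, and the clusters of miR-99, miR-100 and miR-125 3 higher of 5 (0.122). The miR-34 family had 3 lower of 3 (0.238), and the Dlk1-Dio3 cluster 3 lower of 3 (0.364). The miR-29 family had 2 higher and 1 lower (0.514), the nervous system list 1 higher and 4 lower (0.758), and the miR-30 family 1 higher and 2 lower of 5 (0.831), where the median (0.01) and the mean (-0.12) differed in sign.

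Of miRNAs reported to promote breast cancer metastasis, 3 were higher and 6 lower in 4T1 (adjusted p = 0.758; median -0.25, mean 0.16). Against single lines the counts were 3 and 6 for 67NR, 6 and 0 for 168FARN and 6 and 1 for 4TO7. Without the 67NR arrays the mean of its 8 tested members lay 0.61 above that of the other miRNAs, which did not pass (adjusted p = 0.0518 by camera). miR-155, miR-21 (1.52 ± 0.05) and miR-182 were the higher ones, and miR-10b was well above background on all 67NR arrays and at the floor in 4T1. Of those reported to suppress it, 3 were higher and 4 lower of 8 (adjusted p = 0.831; median -0.15, mean -0.05, with the test pointing up). miR-31, a reported suppressor of metastasis, was 2.29-fold higher in 4T1 than the average, by 3.57 ± 0.03 over 67NR and 0.17 ± 0.03 over 168FARN, but lower than in 4TO7, by 0.15 ± 0.03 (adjusted p = 0.00187). The miR-200 family, which holds cells in an epithelial state by repressing Zeb1 and Zeb2, could not be compared, since none of its 5 members was well above background on all arrays of a line. miR-200c read 13.5 ± 3.43 (SD) signal units in 67NR, where it and miR-141 were each well above background on 1 of 3 arrays, while miR-200a read -0.56, miR-200b -1.16 and miR-429 0.71 there, and the 5 read -2.22 to 0.65 in the other lines.

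The 4 passenger strands of the miR-200 family, the 3 liver and pancreas miRNAs and the 10 viral miRNAs could not be tested either. Lists with fewer than 3 tested members gave values only. The differences were those of miR-31* of the other epithelial list (1.09 ± 0.05) and of miR-221 and miR-222 (-0.70 ± 0.07 and -0.39 ± 0.05). The endothelial miR-126-3p was not read in 168FARN, the haematopoietic miR-142-3p (37.8 ± 9.27 (SD) signal units) and the muscle miR-206 were read in 168FARN only, and miR-290-5p of the stem cell clusters was read on all arrays of 67NR only.

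A stricter question was which miRNAs set 4T1 apart from each of the 3 other lines, each of which stands for an earlier step of metastasis. Each step has only 1 line, so in every comparison a difference between steps cannot be told apart from one between lines. 17 miRNAs were higher in 4T1 than in each, and 14 were lower. miR-132 (chromosome 11, 74987231 to 74987246), which the factor CREB switches on in neurons, was 1.22 ± 0.04 over 67NR and at least 7.08-fold over 168FARN and 6.25-fold over 4TO7. miR-301b (chromosome 16, 17124513 to 17124532) was at least 1.32-fold, 2.23-fold and 1.97-fold over them, and miR-181c (chromosome 8, 86702823 to 86702841) at least 1.36-fold, 2.36-fold and 2.08-fold. Its neighbour miR-181d was 0.67, 2.17 and 1.29 over 67NR, 168FARN and 4TO7, and miR-155 was at least 6.22-fold, 0.74 and 2.70 over them. miR-125b-5p (5.61, 1.07 and 0.65) and miR-100 (3.32 over 67NR, 2.30-fold over 168FARN and 0.43 over 4TO7), whose genes lie in related clusters, and miR-23b (0.42, 1.12 and 2.02) and miR-301a (0.15, 0.96 and 0.75) were higher as well.

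From the X-linked gene Clcn5, miR-500 (at least 3.74-fold, then 0.55 and 1.38), miR-362-3p (at least 2.32-fold, then 0.29 and 1.12) and miR-362-5p (0.27, 0.25 and at least 2.30-fold) were higher in 4T1 than in 67NR, 168FARN and 4TO7. miR-674, miR-674*, miR-30b*, miR-21* and miR-101b complete the 17, but miR-30b* was higher than in 67NR only with unread levels at the floor and has no bound there. In 168FARN miR-30b* was at the floor on all arrays too, so its difference from that line (0.38) is one over the floor. miR-155, miR-500, miR-362-3p, miR-674*, miR-21* and miR-101b were read on all 9 other arrays and on no 67NR array. The hypothesis of RNA from another organism on the 67NR arrays, taken up below, bears on their difference from 67NR. Lower in 4T1 than in each were miR-7a (chromosome 13, 58494202 to 58494223), which represses Egfr, by 1.45, 0.64 and 1.58, miR-487b by 2.83-fold, 2.11-fold and 1.66-fold, miR-1224 by 1.90, 0.71 and 0.86, miR-494 by 1.52, 0.58 and 0.73, and miR-9* by 1.96, 1.02 and 0.43. miR-378, which lies in an intron of Ppargc1b, was lower by 2.32, 0.90 and 0.36, miR-101a by 3.68, 0.34 and 0.33, miR-148b by 3.20, 0.57 and 0.29, miR-26a by 1.04, 0.63 and 0.46, and miR-322 by 0.53, 0.68 and 0.63. miR-29c, miR-26b, miR-574-5p and miR-30e complete the 14, and their smallest differences were 0.24, 0.23, 0.21 and 0.19.

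With levels below the floor set to it, only miR-132 and miR-301b differed over 2-fold from each line, and by its bounds only miR-132 did. miR-181c, unread in 67NR, entered there at -4.99, above the floor, and differed by 0.65 from that line. Independent lists of these sizes would share 6.19 miRNAs that are higher and 15.0 that are lower, and simulated arrays without differences, with the 4T1 arrays shared as here, gave 0 in 100 simulations. Under the 3 other scalings 13 of the 17 stayed higher than in each line, miR-125b-5p, miR-21*, miR-362-3p and miR-362-5p being the others, and of the 14 lower ones none stayed in all 3. The lower set held 4 miRNAs with the 75th percentile of all probes, 0 with no scaling and 9 with quantile scaling, so its calls depended on the scaling. The higher set held 32, 28 and 24 miRNAs. With the normexp correction only 5 of the 17 remained higher, and the lower set grew to 60, with 12 of the 14 in it. With a term for the slide 14 of the 17 and 12 of the 14 remained.

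**Figure D2:**
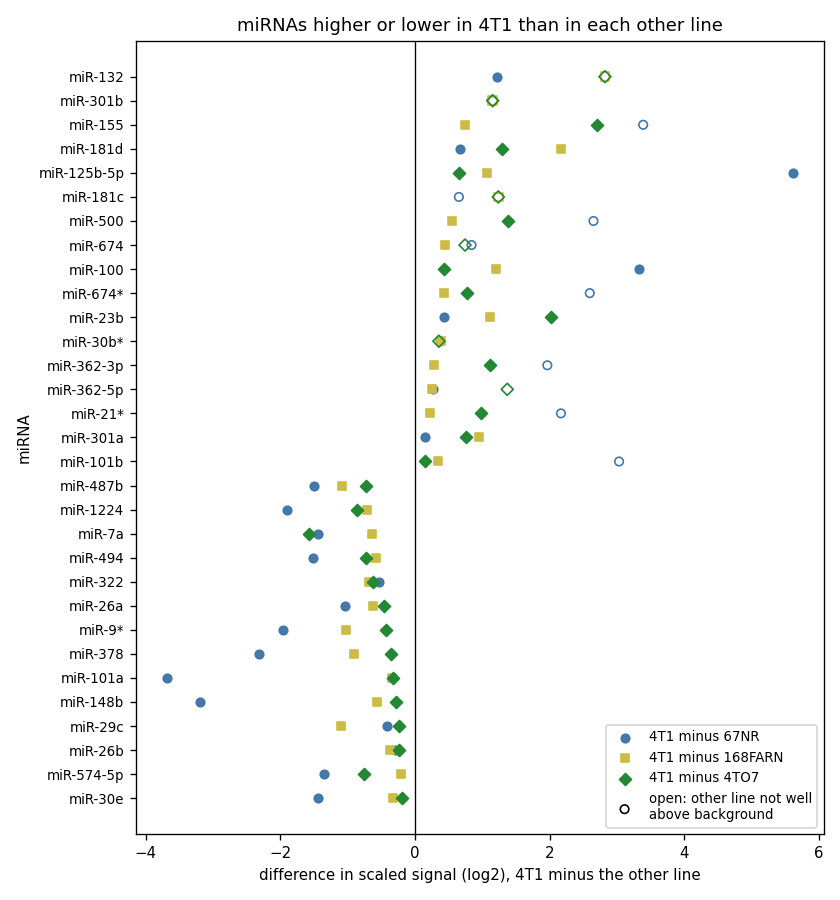
Difference between 4T1 and each other line (x axis, log2 of the scaled signal) for the 17 miRNAs higher and the 14 lower in 4T1 than in each of the 3 lines (y axis). Each point is 1 line, open where that line was not well above background on any array, with levels below the floor set to it. The point of miR-30b* for 168FARN is filled although that line lies at the floor. miR-132 and miR-301b alone lie over 2-fold from all 3 lines.

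Against 67NR, the line that stands for a primary tumour whose cells do not leave it, 4T1 held much more of several let-7 miRNAs and of miR-125b-5p and much less miR-34a. Whether the 67NR arrays carry RNA of another organism, as asked below, is not settled and bears on every comparison with 67NR. let-7i (chromosome 10, 122422754 to 122422774) was 28.5-fold higher in 4T1 (4.83 ± 0.06; adjusted p = 2.40e-14), let-7d 28.3-fold, let-7b 25.2-fold and let-7c 19.7-fold, and miR-125b-5p 48.9-fold (5.61 ± 0.04; adjusted p = 2.59e-16). miR-34a (chromosome 4, 149442584 to 149442603), a target of p53, was 29.3-fold lower (-4.87 ± 0.05; adjusted p = 5.11e-15), at 0.97 ± 0.08 (SD) in 67NR and -3.90 ± 0.03 in 4T1, and miR-148a (chromosome 6, 51219828 to 51219847) was lower by at least 67.8-fold. miR-320 fell 13.2-fold, miR-101a 12.8-fold and miR-128 11.9-fold. The Hox cluster miRNAs miR-10a (chromosome 11, 96178502 to 96178522; at least 75.8-fold), miR-10b (chromosome 2, 74564133 to 74564153; 57.4-fold) and miR-196a (chromosome 11, 96126501 to 96126522; 41.4-fold) were read in 67NR and not in 4T1, as were miR-218 (40.4-fold) and miR-342-3p (39.8-fold). In the other direction miR-130a (chromosome 2, 84581273 to 84581291) was higher in 4T1 by at least 81.6-fold, miR-182 by 12.5-fold, miR-345-5p by 8.32-fold, miR-350 by 6.86-fold and miR-155 by 6.22-fold.

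4 lists were called against 67NR, and none held with the correlation estimated (adjusted p = 0.556 with an estimated correlation in each). All 9 members of the let-7 family were higher (median 2.82, at bounds 2.61; adjusted p = 0.000363), from let-7i to let-7a (0.96 ± 0.06). Of miR-17-92 and its paralogs, the growth-promoting targets of Myc, 11 were lower, 1 was higher and 1 did not pass, of 13 (median -2.69; adjusted p = 0.0332). miR-19a was at -3.36 ± 0.06 and miR-92a at -3.08 ± 0.08, while miR-17 fell by 2.69 ± 0.06 and its passenger strand miR-17* rose at least 5.89-fold. The Sfmbt2 cluster was higher (11 of 13, 2 not passing; median 1.26, at bounds 0.50; adjusted p = 0.000228). The miR-23/24/27 clusters were higher (4 of 5; median 1.98; adjusted p = 0.0477), with miR-23a at 2.64 ± 0.09 and miR-27b, not passing, at 0.18 ± 0.08. The counts adjusted over the list alone were the same. The ranges of the adjusted p over the alternatives of the same test began at 4.12e-10 for let-7, 0.000583 for miR-23/24/27, 0.00704 for miR-17-92 and 1.94e-06 for Sfmbt2 and ended at 0.556. The miR-23/24/27 call also ended without 67NR replicate 1, without 4T1 replicate 2 or without 4T1 replicate 3, with the total gene signal and with the floor halved, and the Sfmbt2 call with the normexp correction.

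In this comparison 178 of 224 miRNAs (79.5%) differed by limma, 72 higher and 106 lower, 131 of them at least 2-fold. Over all 224 tested miRNAs the 3 arrays of each line did not overlap in 182, where chance would give 10% of unselected miRNAs. The 178 were all among these, but they were picked for their difference, so chance is not set against them. The 224 were picked too, for being read on all arrays of a line, so the 10% is not their chance rate. The 67NR arrays, which correlated at only 0.626 to 0.636 with those of 4T1, share no slide with them, so no value within a slide exists. A term for the slide left 174 differing (68 higher and 106 lower), each of the 178 kept its direction, and the list differences moved from 3.44 to 3.51 for let-7, -1.63 to -1.61 for miR-17-92, 1.88 to 1.95 for miR-23/24/27 and 1.84 to 1.88 for Sfmbt2. The split was 90 higher and 87 lower with the 75th percentile of all probes, 104 and 66 with no scaling, 95 and 90 with quantile scaling and 39 and 169 with the normexp correction.

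168FARN stands for cells that enter the vessels but form no metastases, and its comparison with 4T1 asked what separates it from the metastatic line. 4T1 held less of miR-497 (chromosome 11, 70048234 to 70048253; -3.55 ± 0.08, 11.7-fold; adjusted p = 4.71e-12) and of its neighbour miR-195 (chromosome 11, 70048566 to 70048584; -3.12 ± 0.08, 8.70-fold), which share the seed of miR-16. miR-146a (chromosome 11, 43187937 to 43187955), which is switched on by NF-kB, was 11.7-fold lower (-3.54 ± 0.04; adjusted p = 1.26e-14), miR-34a 7.87-fold and miR-181b 2.67-fold. miR-181d was the highest of the miRNAs measured in both lines (2.17 ± 0.11, 4.49-fold; adjusted p = 7.69e-09), followed by 4 members of miR-17-92 and its paralogs, miR-18a (2.67-fold), miR-17 (2.45-fold), miR-17* (2.34-fold) and miR-106a (2.33-fold). Higher by bounds were miR-130b (at least 10.3-fold), miR-193b (7.85-fold), miR-669a (7.64-fold), miR-132 (7.08-fold) and miR-466e-3p (6.70-fold).

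4 lists were called here, and all were lost with the correlation estimated (adjusted p = 0.463 to 0.492 with an estimated correlation). The X-linked cluster was lower in 4T1 than in 168FARN in 16 of 16 (median -2.30; adjusted p = 6.15e-07), led by bounds of at least 14.5-fold for miR-743a, 13.9-fold for miR-741, 8.91-fold for miR-880 and 8.45-fold for miR-883a-3p. miR-465c-3p, which is not on that list, was lower by at least 19.1-fold. The mesenchymal list was lower in 6 of 6 (median -1.77; adjusted p = 0.00456), with miR-199b lower by at least 13.4-fold, miR-143 by at least 2.46-fold and miR-140 at -0.74 ± 0.04. The Sfmbt2 cluster was higher in 11 of 13 (2 not passing; median 1.26; adjusted p = 1.62e-05), and miR-17-92 with its paralogs in 10, with 1 lower and 2 not passing (median 1.06; adjusted p = 0.00314), miR-106b being the lower one (-0.20 ± 0.04). The counts adjusted over the list alone were equal to these. By list the values were adjusted p = 0.492 with an estimated correlation for the X-linked cluster (range over the alternatives of the same test 1.25e-09 to 0.492), for the mesenchymal list (0.00171 to 0.492) and for miR-17-92 (0.00014 to 0.492), and 0.463 for Sfmbt2 (7.41e-08 to 0.463).

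**Figure D3:**
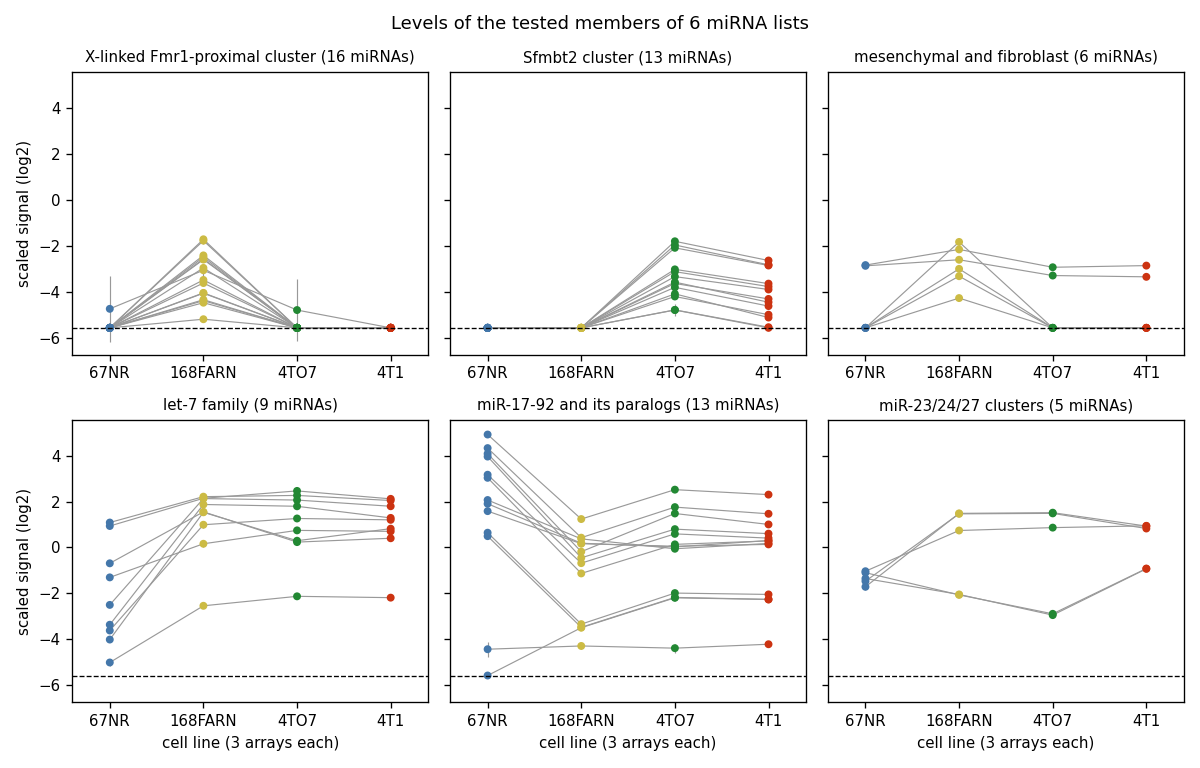
Scaled signal (y axis, log2) of the members of 6 lists in the 4 lines (x axis), each point the mean of 3 arrays with its SD and each line joining the values of 1 miRNA, with the floor of -5.58 dashed. The 16 members of the X-linked cluster rise above the floor in 168FARN and the 13 of the Sfmbt2 cluster in 4TO7. In 4T1 the Sfmbt2 members do so too, except miR-297c at the floor and miR-297b-3p (-5.55) close to it. The let-7 and miR-17-92 panels show 67NR on opposite sides.

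Here 166 of 224 miRNAs (74.1%) differed by limma, 77 higher and 89 lower, 74 of them at least 2-fold, and in 164 of them the arrays did not overlap. Over all 224 tested miRNAs they did not overlap in 172 (chance 10% for unselected miRNAs, which these are not). A slide term left 164 differing (75 higher and 89 lower), and on the slide that holds both lines 162 did (73 and 89), with every direction kept. The list differences there were -2.23 for the X-linked cluster (main -2.23, slide term -2.23), -1.74 for the mesenchymal list (-1.76 and -1.75), 1.71 for Sfmbt2 (1.67 and 1.68) and 1.07 for miR-17-92 (1.05 and 1.05). The split was 93 higher and 73 lower with the 75th percentile of all probes, 69 and 75 with no scaling, 97 and 83 with quantile scaling and 62 and 81 with the normexp correction.

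4TO7 stands for cells that reach distant sites and do not grow there, and it was compared with 4T1 as the line before the last step. The comparison cannot separate that step from other differences between the 2 lines. miR-155 was 6.52-fold higher in 4T1 (2.70 ± 0.06; adjusted p = 1.54e-11), at -2.19 ± 0.03 (SD) against -4.89 ± 0.10. The neighbours miR-23b (chromosome 13, 63401841 to 63401857) and miR-27b (chromosome 13, 63402072 to 63402088) were 4.05-fold (2.02 ± 0.06; adjusted p = 1.37e-10) and 3.92-fold (1.97 ± 0.08) higher. miR-23a (-0.58 ± 0.09) and miR-27a (-0.66 ± 0.05) of the sister cluster were lower and miR-24, made from both clusters, did not pass (0.08 ± 0.03). miR-500 (2.61-fold) and miR-532-5p (2.46-fold) from Clcn5 were higher, and so were, by bounds, miR-132 (at least 6.25-fold), miR-34a (2.82-fold), miR-338-3p (2.71-fold), miR-185 (2.38-fold) and miR-362-5p (2.30-fold). miR-148a, at -2.65 ± 0.04 in 4TO7 and at the floor in 4T1, was lower by at least 7.60-fold, miR-146b by 3.42-fold, miR-449a by 2.22-fold and miR-152 by 2.01-fold. miR-7a fell 2.98-fold (-1.58 ± 0.05; adjusted p = 3.60e-10) and miR-340-5p 2.61-fold.

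The Sfmbt2 cluster was lower in 4T1 than in 4TO7 in 13 of 13 (median -0.78; adjusted p = 1.36e-06), from miR-466c-5p (-1.03 ± 0.04) to miR-467a (-0.56 ± 0.04), and the count adjusted over the list alone was 13 as well. The call did not hold with the correlation estimated: adjusted p = 0.267 with an estimated correlation (range over the alternatives of the same test 2.07e-09 to 0.267), and it ended with the normexp correction. With no scaling its median was -0.10 and none of its members passed by limma (1 of 13 at an unadjusted p below 0.05). In the miR-23/24/27 clusters 2 were higher and 2 lower over all tested miRNAs, and 3 and 2 adjusted over the list alone. With the normexp correction miR-532-5p (0.17), miR-338-3p (0.12) and miR-185 (0.03) no longer passed and miR-362-5p turned to -0.01, and with the floor doubled miR-152 (-0.03) no longer passed.

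Here 136 of 224 miRNAs (60.7%) differed by limma, 56 higher and 80 lower, but only 22 at least 2-fold, 14 higher and 8 lower. In all 136 the arrays did not overlap, and over all 224 tested miRNAs they did not in 152 (chance 10% for unselected miRNAs, which these are not). With slide as a term 135 differed (56 and 79), and within the slide that holds both lines 138 did (55 and 83). All arrays of both lines lie on that slide, so these fits give each miRNA the same difference as the main one. The kept directions and the Sfmbt2 list difference of -0.77 in all 3 are therefore no check of the slide. The split was 80 higher and 40 lower with the 75th percentile of all probes, 105 and 7 with no scaling and 26 and 167 with the normexp correction.

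The step from 67NR to 168FARN, from cells that stay in the tumour to cells that enter vessels, had the most miRNAs that differed at least 2-fold. let-7i was 46.6-fold higher in 168FARN (5.54 ± 0.06; adjusted p = 6.32e-15), let-7b 37.8-fold, let-7c 24.8-fold, miR-709 24.5-fold and let-7d 24.4-fold. miR-19a was 21.3-fold lower (-4.41 ± 0.06; adjusted p = 1.49e-14), miR-92a (chromosome 14, 115443702 to 115443718) 19.3-fold, miR-18a (chromosome 14, 115443093 to 115443111) 17.9-fold and miR-320 17.4-fold. Bounds were at least 78.6-fold higher for miR-130a, 13.9-fold for miR-350, 11.3-fold for miR-465c-3p, 10.3-fold for miR-182 and 8.59-fold for miR-743a. In the other direction they were at least 67.8-fold lower for miR-148a, 57.4-fold for miR-10b, 42.6-fold for miR-130b, 41.4-fold for miR-196a, 40.4-fold for miR-218 and 22.9-fold for miR-590-5p.

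None of the 4 list calls of this step held with the correlation estimated (adjusted p = 0.573 with an estimated correlation in each). The X-linked cluster was higher in 168FARN in 16 of 16 (median 2.02, at bounds 1.29; adjusted p = 2.63e-05), let-7 in 9 of 9 (2.47, at bounds 2.25; adjusted p = 0.00239) and the mesenchymal list in 6 of 6 (1.77, at bounds 1.09; adjusted p = 0.0236), with miR-199a-5p higher by at least 3.52-fold. Of miR-17-92 and its paralogs 11 were lower, 1 higher and 1 not passing (median -3.85; adjusted p = 0.0133). The counts adjusted over the list alone did not differ from these. The ranges of the adjusted p over the alternatives of the same test ended at 0.573 and began at 1.87e-06 for the X-linked cluster, 9.06e-08 for let-7, 0.00919 for the mesenchymal list and 0.00333 for miR-17-92. No scaling, the normexp correction and the total gene signal also ended the mesenchymal call.

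By limma 197 of 224 miRNAs (87.9%) differed, 90 higher and 107 lower, 153 of them at least 2-fold, and in 193 of them the arrays did not overlap. Over all 224 tested miRNAs they did not overlap in 194 (chance 10% for unselected miRNAs, which these are not). The 67NR arrays correlated at 0.539 to 0.551 with those of 168FARN. The fit with a slide term called 193 (86 and 107), with every direction kept, and rests on 168FARN replicate 1 for the step between slides. Within the first slide 168FARN is that 1 array beside the 3 of 67NR, without a measure of spread in 168FARN, so no count is given. All 197 directions were kept there, but these arrays also serve in the main fit. The list differences there were 2.57 for the X-linked cluster (main 2.54, slide term 2.54), 3.55 for let-7 (3.47 and 3.52), 2.05 for the mesenchymal list (2.02 and 2.03) and -2.66 for miR-17-92 (-2.67 and -2.67). With no scaling 107 were higher and 72 lower, and with the normexp correction 48 and 154.

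In the step from 168FARN to 4TO7, the lines that stand for entry into vessels and for arrival at distant sites, 2 clusters differed in opposite directions. All 4 list calls of this step were lost with the correlation estimated: adjusted p = 0.191 with an estimated correlation for Sfmbt2 (range over the alternatives of the same test 1.72e-14 to 0.191), 0.512 for the X-linked cluster (4.95e-08 to 0.512) and the mesenchymal list (0.00213 to 0.512) and 0.595 for miR-17-92 (0.00745 to 0.595). The Sfmbt2 cluster was higher in 4TO7 in 13 of 13 (median 1.99; adjusted p = 1.71e-07), with bounds of at least 13.6-fold for miR-669a (chromosome 2, 10396089 to 10396108), 12.2-fold for miR-466e-3p and 11.2-fold for miR-467a*. The X-linked cluster was lower in 16 of 16 (median -2.02, at bounds -1.84; adjusted p = 4.38e-07), with bounds of 12.8-fold for miR-743a and 12.3-fold for miR-741, and miR-465c-3p outside the list at 16.9-fold. The mesenchymal list was lower in 6 of 6 (median -1.77, at bounds -1.59; adjusted p = 0.0063). miR-17-92 with its paralogs was higher in 9, lower in 2 and not passing in 2 (median 1.27; adjusted p = 0.0147), with miR-92a 3.17-fold (1.66 ± 0.08; adjusted p = 2.60e-09), miR-17 (chromosome 14, 115442915 to 115442928) 2.55-fold and miR-20a 2.52-fold higher. Further miRNAs higher in 4TO7 were miR-99a (2.89-fold), miR-183* (2.77-fold) and, by bounds, miR-193b (at least 10.8-fold) and miR-148a (7.60-fold). miR-195 was 11.8-fold lower (-3.57 ± 0.08; adjusted p = 6.52e-12), miR-155 3.91-fold, miR-99b* 2.65-fold, let-7e 2.49-fold and let-7i 2.36-fold, and by bounds miR-34a at least 22.2-fold and miR-497 15.2-fold.

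The counts adjusted over the list alone equalled those over all tested miRNAs. By limma 167 of 224 miRNAs (74.6%) differed, 79 higher and 88 lower, 73 of them at least 2-fold, and in 161 of them the arrays did not overlap. Over all 224 tested miRNAs they did not overlap in 164 (chance 10% for unselected miRNAs, which these are not). With slide as a term 158 differed (75 and 83), and within the slide that holds both lines 159 did (75 and 84), every direction being kept. Within it the list differences were 2.48 for Sfmbt2 (main 2.44, slide term 2.45), -2.23 for the X-linked cluster (-2.23 and -2.22), -1.79 for the mesenchymal list (-1.80 and -1.80) and 1.08 for miR-17-92 (1.06 and 1.06). With no scaling 38 were higher and 127 lower, and with the normexp correction 123 and 52.

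Over all 4 lines 217 of 224 miRNAs (96.9%) differed by limma's F-test. Some were read on all 3 arrays of 1 line and on no other array. Of these 25 belonged to 168FARN, 14 to 67NR (miR-192, miR-194, miR-196a, miR-218 and miR-551b among them), 2 to 4T1 (miR-181c and miR-301b) and 0 to 4TO7. The reverse, a miRNA read on all 9 arrays of the other lines and on none of its own, was found for 20 in 67NR (miR-130a, miR-155, miR-182, miR-101b, miR-98 and miR-500 among them), 5 in 168FARN (miR-126-3p, miR-130b, miR-193b, miR-340-3p and miR-340-5p), 6 in 4TO7 (miR-34a, miR-181b, miR-185, miR-362-5p, miR-497 and miR-532-3p) and 0 in 4T1.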

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

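The tests of RNA from another organism and of lower signal were chosen only after the result was seen, while that of the slide was planned before.

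4 control probes named hur_5 gave a signal that no comparison uses. Their mean was 180 to 206 units on the 3 arrays of 67NR and 1.25 to 6.36 on the other 9, so the lowest 67NR array read 28.3 times the highest other array. 168FARN replicate 1, on the same slide as 67NR, read 1.25. Of the other controls, hur_1 read 3.73 times the mean of the other lines in 67NR, hur_2 1.24, hur_4 1.40, hur_6 0.748 and mr_1 1.04 times, and the files do not say what these names stand for. The 67NR arrays stand apart in their miRNAs too, with a correlation of 0.539 to 0.636 with other lines against 0.837 or more among those lines.

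A slide of its own could set 67NR apart. Over the miRNAs that differed between 168FARN and 67NR, the slope of 168FARN replicate 1 on 67NR, both taken from the 168FARN arrays of the other slide, was -0.00435 (95% interval -0.0100 to 0.000510). A slide effect predicts a slope near 1, so the value argues against the slide. It rests on that 1 array, and its interval resamples miRNAs and holds no spread between arrays or slides. Lower signal could hide miRNAs on these arrays. The 20 miRNAs read on all 9 other arrays and on no 67NR array had levels that lay a median of 1.52 (log2; 95% interval 0.877 to 2.15) above the lowest level read there (-4.82), and 19 of the 20 lay above it. A level above that lowest one can still go unread, as miR-878-3p did on 67NR at -4.75 ± 1.43 (SD). The values therefore argue against lower signal only for miRNAs far above it, such as miR-130a (6.28) and miR-182 (3.70), and leave it open for the others. RNA of another organism, such as a human line in place of or mixed with 67NR, is a hypothesis that 1 test favours: of miRNAs read on all other arrays, 8 of 11 with no human counterpart by name (72.7%) were missing on 67NR against 12 of 108 others (11.1%; odds ratio 20.3, 95% interval 4.20 to 135; Fisher's exact p = 1.95e-05). Counted by number, with miR-101b among the others since a human miR-101 exists, 7 of 10 were missing against 13 of 109 (odds ratio 16.5, 95% interval 3.29 to 112). The list of 94 names was drawn up after the missing miRNAs had been seen, miR-697, miR-709 and miR-712 were read on 67NR all the same, and a true difference of the line from the others stays open and untested.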

How the results depend on the processing

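The fits without the 67NR arrays and with a term for the first place of a row are tests chosen only after the result was seen. Signal over background limits these results, since 224 of 577 miRNAs could be tested, levels below the floor of -5.58 were set to it, and the 67NR arrays read no level below -5.08 to -4.64. With 1 array left out, 193 to 199 miRNAs differed between 4T1 and the mean, 177 to 180 between 4T1 and 67NR, 159 to 168 between 4T1 and 168FARN, 129 to 139 between 4T1 and 4TO7, 192 to 196 between 168FARN and 67NR and 158 to 168 between 4TO7 and 168FARN. The sets higher and lower than each line held 17 to 19 and 13 to 16 miRNAs, 216 to 219 differed among the 4 lines, and 4 lists were called each time. The replicate numbers do not pair arrays across lines (6 of 18 same-numbered pairs had a correlation over 0.1, from -0.796 to 0.556, and 1 of 12 arrays matched its own number best), and as a replicate block they gave 195, 178, 166, 135, 194 and 163 miRNAs in the order above, sets of 17 and 14, 216 among the lines and 4 lists.

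The set higher in 4T1 than in each line held 32 miRNAs with the 75th percentile of all probes, 28 with no scaling, 5 with normexp, 5 with the filter for all 12 arrays, 2 at a difference of at least 1 and 36 without the 67NR arrays. The lower set held 4, 0 with no scaling, 9 with quantile, 60 with normexp, 26 with the gene-level total signal, 0 at a difference of at least 1 and 37 without the 67NR arrays. The scalings move the median of the bright miRNAs by construction: in 4T1 against the mean by 0.71 (none), 0.41 (75th percentile of all probes) and 0.33 (quantile). The filter for all 12 arrays tests only 96 miRNAs and so called fewer: 82, 87, 78, 70, 91 and 75 in the 6 comparisons and 92 among the lines. A difference of at least 1 left 66 for the mean, 74 for 168FARN, 22 for 4TO7 and 73 between 4TO7 and 168FARN. Of the lists, 2 were called with the floor doubled, 0 with an estimated correlation and 15 with fry, which asks another question. The cause of the other moves was not tested.

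In the differences of 4T1 from the mean, some members of lists changed sign. With no scaling miR-140 was at 0.28, miR-140* at 0.49, miR-20b at 0.0900, miR-20a at 0.00434, miR-106b at 0.0909, miR-19b at 0.12, miR-15a at 0.18, miR-322 at 0.0948, miR-15b at 0.43, miR-29c at 0.12, miR-30e at 0.0590, miR-30c at 0.37, miR-125a-5p at 0.63, miR-99a at 0.68, miR-221 at 0.00401, miR-222 at 0.32, miR-126-3p at 0.33 and miR-9 at 0.45. With the 75th percentile of all probes miR-140* was at 0.19, miR-15b at 0.13, miR-30c at 0.0715, miR-125a-5p at 0.33, miR-99a at 0.38, miR-222 at 0.0206 and miR-9 at 0.15, and with quantile scaling miR-140* at 0.0729, miR-19b at 0.0136, miR-15b at 0.16, miR-125a-5p at 0.16, miR-99a at 0.36 and miR-9 at 0.15. The cause of the single moves was not tested.

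Without the 67NR arrays only 168FARN and 4TO7 are left in the mean, and miR-182 was at -0.0809, miR-96 at -0.19, miR-20b at 0.45, miR-20a at 0.37, miR-19a at 0.43, miR-106b at 0.0180, miR-19b at 0.42, let-7i at -0.0931, let-7c at -0.30, let-7b at -0.55, miR-15a at 0.17, miR-15b at 0.0172, miR-29a at -0.82, miR-29b at -0.74, miR-27a at -0.65, miR-23a at -0.57, miR-99b at -0.13, miR-99a at 0.12, miR-221 at 0.18, miR-222 at 0.45, miR-126-3p at 0.52 and miR-9 at 0.0726. Taken against the other tested miRNAs, the means of miR-17-92 (0.53), let-7 (-0.0313), the miR-29 family (-0.63), the nervous system list (0.21) and the list reported to suppress metastasis (-0.20) turned as well.

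miR-30d, at 0.01 in the report's fit, was at -0.21 with normexp, -0.24 with the gene-level total signal, -0.00821 with the mean of all probes, -0.14 with a slide term, -0.00474 with the first-place term and -0.00165 without 67NR replicate 2, -0.0313 without 168FARN replicate 1, -0.0143 without 4TO7 replicate 3 and -0.0642 without 4T1 replicate 3, the lowest with 1 array left out, against a highest of 0.0509 without 4T1 replicate 1. The gene-level total signal put miR-96 at -0.11 and miR-30a at -0.0637, the first-place term put miR-99a at 0.00611, and normexp put miR-362-5p between 4T1 and 4TO7 at -0.0133. The cause was not tested. The other results kept their direction, and the list calls that ended are named with the comparisons.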

Other observations

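The tests of the Sfmbt2 cluster and of the first place of a row were chosen only after the result was seen, while the regroupings of the arrays were planned before.

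The Sfmbt2 cluster, silent at this limit in 67NR and 168FARN, could appear in 4TO7 and 4T1 as 1 RNA that the related probes of every member read. The 4T1 minus 4TO7 differences of its 13 tested members ran from -1.03 to -0.56, and their variance was 7.96 times the mean squared standard error (95% interval 2.09 to 17.8). Members near the floor are compressed there, so the ratio was taken again, once the first was known, over the 8 members at least 1 (log2) above the floor on all arrays, and was 12.6 (4.30 to 18.3). A standard error over arrays leaves out how far 2 probes of 1 miRNA differ, a median of 0.05 over 98 other miRNAs in this comparison. Against the variance between such probes, also taken later, that of the members was 3.94 times as large (1.29 to 6.73), so the values cannot tell whether 1 RNA or several were read. miR-297a, on the list by its name, has its probe target on chromosome 10 (42855314 to 42855332), away from the other 12 members.

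The arrays 67NR replicate 1, 168FARN replicate 2 and 4TO7 replicate 3, each in the first place of a row on its slide, moved together in 11 miRNAs, 4 higher and 7 lower, with miR-697 (2.11), miR-202-3p (1.77) and miR-878-3p (1.74) over 2-fold. An effect of the place on the slide may explain this: of the 27 choices of 1 array from each of these 3 lines, only this 1 gave as many miRNAs, and the highest of the other choices gave 0. The 4T1 arrays hold no such place and the count was known before the test was written. miR-27b (-0.21), miR-23a (-0.20), miR-221 (-0.20) and miR-26b (-0.13) are also among the 11, so values of these in the report would carry such an effect as well.

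Chance in the grouping could give counts of this size where the arrays differ for any reason. Over 100 groupings of the 12 arrays into 4 sets of 3, the real one included, 1 gave as many miRNAs differing between 4T1 and the mean (real 196, highest other 141). As many were higher in 4T1 than in each line in 3 (17, highest other 87) and lower in 2 (14, highest other 43). As many differed among the 4 lines in 1 (217, highest other 169). For the counts of 196 and 217 this shows that arrays group by sample, as correlations of 0.993 or more within a line also do. It cannot exclude chance between samples, since the repeats of a line may be technical. The grouping that gave 87 and 43 far exceeds the real 17 and 14, which points to structure of the samples, and for these 2 sets chance is left open. For the 4 lists called in the mean comparison chance cannot be excluded, as 31 of the 100 groupings called as many (highest other 5). For each pair of lines 1 of 10 groupings, the real one, gave as many (178, 166, 136, 197 and 167, highest other 0 in each), and 10 are too few to tell. The 4T1 arrays serve in each of the 3 comparisons and cannot be split into sets, so part of the excess of miRNAs higher than in each line (17 against 6.19 for independent lists) may come from them. The lower set shows no excess (14 against 15.0), and simulated arrays without differences, which gave 0, show only that noise alone shares none.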
